A study of Rattus norvegicus with 399 samples.

How the data were processed

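TempO-Seq libraries of the Rat S1500+ panel were analysed from heart, kidney, liver, lung and ovary of 9-week-old female Sprague-Dawley rats. In this targeted assay a pair of detector oligonucleotides binds side by side on a transcript, is ligated, and is amplified and sequenced, so that a read is counted for a chosen stretch of a chosen transcript. The animals had been given 1,2-dichlorobenzene (1,2-DCB) or 1,4-dichlorobenzene (1,4-DCB), and tissues were collected on study day 5 into RNAlater and extracted with QIAzol, per the labels. The exposure route and the daily hours of exposure and collection are not given in the sources used here. Groups were taken from the labelled compound, concentration and tissue. The letter F and number in each title name the rat (F101, for example; numbers 1 to 10 are controls), so libraries of different tissues come from the same rat, and each compound had its own control rats.

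The values deposited by the authors are attenuation-adjusted raw read counts, 1 count per probe and library. The submitters' processing notes name Bowtie 1.3.1 for alignment. Its settings, the probe reference and the genome build are not given in the sources used here, so no coordinates are reported. Attenuation means that oligonucleotides of very abundant transcripts are diluted before sequencing, after which the authors multiplied those counts back up. In the table, 104 of 2654 probes held only whole multiples of a step between 3 and 10, 22 of them of 10, and 16 probes were 0 in every library. Such scaling leaves fold changes as they are but enlarges the totals and the counting noise of these probes. The probes carry 2603 gene symbols, of which 2405 are current RefSeq symbols of the rat, 99 are older symbols and 99 were not matched. Genes are named by the symbol in the probe name. Whether a probe separates close paralogs (such as Cyp2b1 and Cyp2b2, or members of the Cyp3a, Cyp4a, Gsta, Gstm and Ugt2b families) is not given in the sources used here, so the member named there is uncertain.

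Of 399 libraries, the submitters mark 9 as not used in their own work: 5 for depth, 2 for alignment rate and 2 as outliers. The same 390 libraries were used here, and the 9 others entered only an alternative. No columns were identical, and the highest correlation between 2 libraries was 0.9884. Totals of the used libraries ran from 1.2 to 69.8 M counts (median 22.6 M), or from 0.543 to 19.4 M (median 7.83 M) after dividing each probe by its step. PCR reads without molecular identifiers are not independent molecules, so these totals bound counting error only.

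Levels are given as CPM, counts scaled to a common library total. Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each tissue and compound, all 7 groups entered a single quasi-likelihood fit (robust, TMM normalization, probes kept by filterByExpr), and each of the 6 concentrations was compared with the compound's own controls. This gave 10 fits and 60 counts of called probes. A probe was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. The compounds were compared by the difference of their changes against their own controls at 1 ppm, at 10 ppm and at 500 against 400 ppm, and their controls were compared with each other, which gave 20 further counts. Tissues were compared by the change in liver minus the change in each other tissue at the top concentration. This used a joint fit of all tissues of a compound, normalized together. Overlaps of called probes between compounds were tested with a one-sided Fisher exact test over the probes tested in both.

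The 21 gene lists and 12 lists of cell type markers were written before the data were examined, as were the tests, the threshold and the rule for named genes. Lists were tested at the top concentration with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Their p-values were adjusted over the lists within each tissue and compound, and the test was repeated with an estimated correlation. Counts of called members, which are counts of probes, were also adjusted over the list alone. By the rule for named genes, those named at the top concentration were the 8 largest rises and the 8 largest falls among called probes with a mean of at least 20 CPM in either group, with 1 probe per gene, plus up to 4 called members of each list with the smallest p. Some genes that meet it are not reported here. A gene named in 1 tissue or compound may be given in the others for comparison. The lowest concentration at which a gene was called is the lowest with every higher concentration also called in the same direction. Levels are means of CPM ± SD and changes are log2 fold changes ± SE of the fit. Counts written with an exponent, such as 1.1e+02, are rounded to the digits shown.

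Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in the edgeR fit, limma voom, a filter at a mean of 20 CPM, no filter, a fit of only the exposed group and its controls, all libraries, leaving out each exposed library, a stricter threshold of 0.01 for the overlaps, and the animal number as a replicate block for the tissue comparison. Chosen after seeing the data were leaving out each control library, dividing counts by the probe's step, and leaving out libraries that stood apart. A library stood apart when its median correlation with libraries of its tissue lay over 5 robust SDs below the tissue's median (liver was left out of this rule), or when its total was under 1 in 10 of the median of its tissue and compound. The pairing of tissues by animal number comes from the titles and was checked with the 60 most variable probes: the mean correlation was between 0.416 and 0.577 for libraries of the same animal and between -0.138 and -0.0782 for libraries of different animals. The pipeline was tested on simulated data in which 200 probes were changed by 1.5, 2 or 4 times. Over the 10 fits it recovered 86.4 to 100% of those changed 4-fold and 38.8 to 67.2% of those changed 1.5-fold, with 0 on the wrong side. Between 4 and 14 unchanged probes were called per fit. Probes were drawn independently, with rises and falls at random and no libraries standing apart. The simulation therefore does not test fits with such libraries, or fits in which most probes change.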

Results

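Female rats received 1,2-dichlorobenzene (1,2-DCB) or 1,4-dichlorobenzene (1,4-DCB), benzene rings with a pair of chlorine atoms that are neighbours in the former and opposite each other in the latter. Concentrations were 1, 10, 30, 100, 250 and 500 ppm of 1,2-DCB and 1, 10, 50, 150, 400 and 800 ppm of 1,4-DCB, each compound beside its own controls, and heart, kidney, liver, lung and ovary were profiled on study day 5. The comparisons ask which transcripts changed in each tissue, from which concentration on, and whether the compounds and the tissues differed. Most groups held 10 control or 5 exposed animals. Exceptions were 9 controls in 1,2-DCB kidney, 8 controls in 1,4-DCB lung, 4 animals in 1,2-DCB lung at 500 ppm, in 1,4-DCB kidney at 1 ppm and in 1,4-DCB lung at 1, 10 and 150 ppm, and 3 animals in 1,4-DCB lung at 400 ppm.

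Depth differed between tissues. Median totals for 1,2-DCB and 1,4-DCB were 13.5 and 12.7 M counts in heart, 34.3 and 25.2 M in kidney, 39.5 and 45.2 M in liver, 18.2 and 25.4 M in lung, and 18.1 and 30.0 M in ovary. The lowest total was 1.2 M, in a 1,4-DCB control ovary. A few transcripts took much of each library. Myl2, a myosin light chain of heart muscle, held 33.5% of the counts in heart, Tf (transferrin) 23.8% in liver, S100a6 17.5% in lung, and the chaperone Hspa8 13.5% in kidney and 14% in ovary.

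The top concentration changed transcripts in every tissue tested, and liver held the most called probes there and at the concentration next below. At 500 ppm of 1,2-DCB, 67.8% of 2019 tested probes were called in liver (1368 probes), 16.4% of 2363 in kidney, 12% of 2092 in heart, 8.85% of 2306 in lung and 2.91% of 2300 in ovary. At 800 ppm of 1,4-DCB, 34.9% of 2019 were called in liver (704 probes), 8.47% of 2386 in ovary, 6.86% of 2054 in heart, 5.91% of 2334 in lung and 5.03% of 2325 in kidney. Next below the top, 500 probes were called in liver at 250 ppm of 1,2-DCB and 130 in liver at 400 ppm of 1,4-DCB, against at most 5 in any other tissue. A change above 2-fold was seen in 645 of the 1368 liver probes called at 500 ppm of 1,2-DCB and in 172 of the 704 called at 800 ppm of 1,4-DCB.

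**Figure D1:**
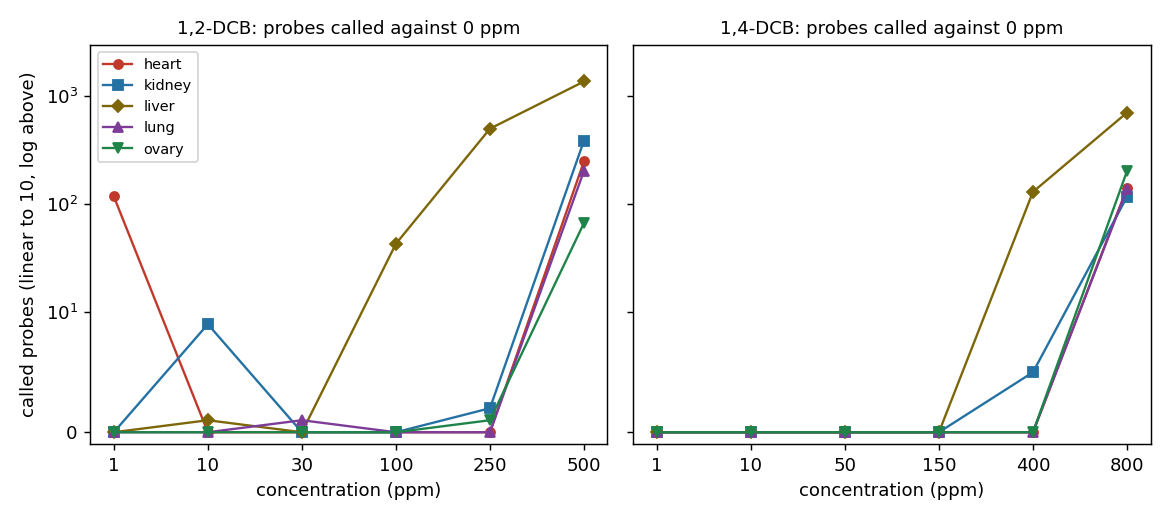
Number of called probes (edgeR, adjusted p below 0.05) on the vertical axis, linear to 10 and logarithmic above, against concentration in ppm on the horizontal axis, with a panel per compound and a line per tissue, with 3 to 5 exposed and 8 to 10 control animals per comparison. Liver reached 1368 probes at 500 ppm of 1,2-DCB and 704 at 800 ppm of 1,4-DCB, while 40 of the 60 comparisons gave 0.

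In liver at 500 ppm of 1,2-DCB, NRF2 target, heat shock and cell cycle lists rose on balance, and lipid synthesis and acute phase lists fell, but only the NRF2 list also passed with an estimated correlation. Gstp1, a glutathione S-transferase, rose from 3.04 ± 0.76 to 115.4 ± 27.3 CPM (SD, n = 10 and 5; log2 fold change 5.25 ± 0.29, adjusted p = 1.99e-17). Akr7a3, an aldehyde reductase, rose from 4.3 ± 1.28 to 169 ± 27.9 CPM (5.29 ± 0.23, adjusted p = 8.83e-21), and the small heat shock protein Hspb1 from 3.77 ± 1.03 to 134.1 ± 40 CPM (5.15 ± 0.22, adjusted p = 7.76e-21). Fabp1, which carries fatty acids in hepatocytes, fell from 12100 ± 2090 to 2730 ± 1030 CPM (-2.15 ± 0.17, adjusted p = 8.17e-14), and C3, the central complement component, from 14600 ± 1700 to 5420 ± 612 CPM (-1.43 ± 0.088, adjusted p = 3.45e-17). In each of these changes 5 of 5 exposed animals lay beyond every control.

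Targets of NRF2, the regulator of antioxidant genes, rose in 1,2-DCB liver in 29 of 30 measured members (30 adjusted over the list alone), among them Cbr1 (3.27 ± 0.097), Txnrd1 (2.56 ± 0.14) and Ugdh (1.91 ± 0.087). List members are counted as probes, and some genes have more than 1. For lists, the adjusted p with the preset correlation is followed by that with an estimated correlation, here adjusted p = 7.77e-14 and 0.000723. Cell cycle genes rose in 31 of 34 and fell in 1 (the same adjusted over the list alone), including the helicase subunits Mcm2 (1.42 ± 0.13) and Mcm3 (2.16 ± 0.23). The list had adjusted p = 6.94e-05 and 0.265. Of the heat shock genes 9 of 9 rose (9 adjusted over the list alone; adjusted p = 0.000615 and 0.172). Of the p53 targets 7 of 11 rose, with the p53 ligase Mdm2 at 1.93 ± 0.11, and 1 fell (the same adjusted over the list alone; adjusted p = 0.0327 and 0.172). Targets of CAR and PXR, the receptors that induce drug-metabolizing enzymes, rose in 15 and fell in 2 of 20 (the same adjusted over the list alone; adjusted p = 0.000247 and 0.108). The exporter Abcb1b reached 5.57 ± 0.29 and Gsta2, which the NRF2 list also holds, 2.26 ± 0.13. In every tissue these lists overlap. Of the symbols on the panel, 13 of 31 for NRF2 and 8 of 21 for CAR and PXR also stand in other lists. For conjugation enzymes it is 8 of 17, so results of lists that share genes are not independent.

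The lists that fell in 1,2-DCB liver passed only with the preset correlation. Of 16 cholesterol synthesis genes 14 fell (14 adjusted over the list alone), among them Cyp51 (-1.98 ± 0.18), Fdps (-1.61 ± 0.20) and Lss (-1.62 ± 0.21). The list had adjusted p = 0.000267 and 0.265. Of 13 fatty acid synthesis genes 12 fell, with Fasn at -1.85 ± 0.26, and Me1, which the NRF2 list also holds, rose by 1.58 ± 0.19 (the same adjusted over the list alone; adjusted p = 0.00422 and 0.242). Inflammation and acute phase genes fell in 13 and rose in 2 of 27, with fibrinogen Fga at -1.43 ± 0.13 and Crp at -1.75 ± 0.17 (the same adjusted over the list alone; adjusted p = 0.0125 and 0.174). Interferon response probes fell in 13 and rose in 1 of 19 (the same adjusted over the list alone; adjusted p = 0.0327 and 0.414). Matrix genes such as Fn1 (-1.56 ± 0.12) fell in 9 of 15 (9 adjusted over the list alone; adjusted p = 0.04 and 0.319). Hepatocyte markers fell in 9 of 10 and Apoa1 rose (the same adjusted over the list alone; median -0.84, adjusted p = 0.00731 and 0.197).

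Along the 1,2-DCB series in liver, most probes were called only at the top. Of the probes called at 500 ppm, 31 were called from 100 ppm on, 376 from 250 ppm on and 961 only at 500 ppm. From 100 ppm on, Abcc3, an exporter of conjugates, rose (1.18 at 100 ppm, adjusted p = 0.000198, and 2.90 ± 0.18 at 500 ppm), as did Gstp1 (1.22, adjusted p = 0.0191), Gsta2 (0.59, adjusted p = 0.0153) and the peroxisomal thiolase Acaa1a (0.50, adjusted p = 0.0398), while Inhba, an activin subunit, fell (-0.57, adjusted p = 0.0356). At 100 ppm 30 probes rose and 13 fell, at 250 ppm 273 rose and 227 fell, and at 500 ppm 707 rose and 661 fell. The count of 43 at 100 ppm was 26 without control F8, 12 without animal F403 and 16 without animal F404. At 10 ppm the only call was Abcc3 (1.09 ± 0.18, adjusted p = 0.00104), which was named after its value was seen. That count of 1 was 2 without control F1, 4 without animal F205 and 0 with a filter at 20 CPM.

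**Figure D2:**
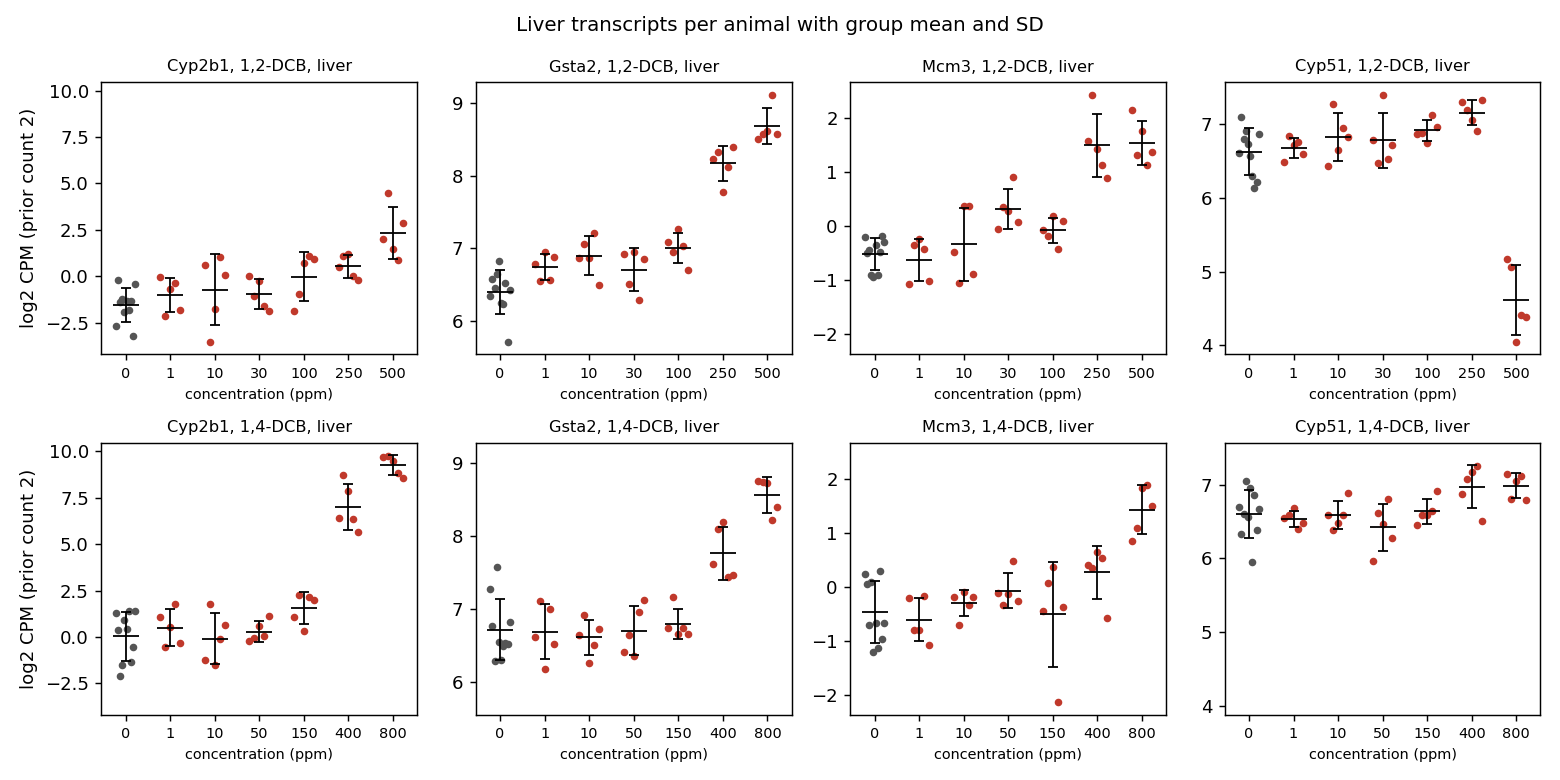
Log2 CPM (prior count 2) of Cyp2b1, Gsta2, Mcm3 and Cyp51 in liver on the vertical axis against concentration in ppm on the horizontal axis, a panel per gene and compound. Points are animals (10 controls, grey, and 5 per concentration, red), and bars are group means with SD. Cyp51 fell by 1.98 on the log2 scale at 500 ppm of 1,2-DCB, and Cyp2b1 rose by 8.85 at 800 ppm of 1,4-DCB.

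At 800 ppm of 1,4-DCB, liver was marked by cytochrome P450 transcripts that CAR induces. Cyp2b1 rose from 1.36 ± 0.982 to 643 ± 215 CPM (SD, n = 10 and 5; 8.85 ± 0.57, adjusted p = 2.71e-14), Cyp2b2 from 6.91 ± 4.76 to 576 ± 207 CPM (6.39 ± 0.50, adjusted p = 5.02e-12) and Cyp3a2 from 807 ± 192 to 5600 ± 1500 CPM (2.79 ± 0.24, adjusted p = 1.53e-11). Aldh1a1, an aldehyde dehydrogenase, rose from 993 ± 186 to 7840 ± 2090 CPM (2.98 ± 0.16, adjusted p = 1.34e-17). Among falls, the insulin-repressed gene Igfbp1 decreased from 36.8 ± 24.3 to 8.33 ± 3.71 CPM (-2.15 ± 0.53, adjusted p = 0.00156) and Glul, glutamine synthetase of the cells around the central vein, from 53.1 ± 11.4 to 22.2 ± 2.99 CPM (-1.25 ± 0.13, adjusted p = 3.91e-10). For each of these genes 5 of 5 exposed animals lay beyond every control.

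Of the CAR and PXR targets, 17 of 21 rose and 0 fell in 1,4-DCB liver (17 adjusted over the list alone; adjusted p = 1.03e-16 and 0.00472). NRF2 targets rose in 28 of 29 (28 adjusted over the list alone; adjusted p = 1.42e-20 and 0.000198), with Akr7a3 at 3.32 ± 0.27 and Gstp1 at 2.91 ± 0.34. Conjugation enzymes rose in 12 of 16 (12 adjusted over the list alone; adjusted p = 4.7e-05 and 0.0105). Cell cycle genes rose in 32 of 33 (33 adjusted over the list alone), with Racgap1 at 2.72 ± 0.36, Aurka at 1.69 ± 0.23 and Pcna at 0.93 ± 0.093. The list had adjusted p = 3.57e-17 and 0.0296. Fatty acid synthesis genes rose in 11 of 13, among them the elongase Elovl6 (2.26 ± 0.21) and Acly (1.36 ± 0.15), and 1 fell (11 rose and 2 fell adjusted over the list alone; adjusted p = 8.38e-06 and 0.0323). Cholesterol synthesis genes such as Acat2 (1.31 ± 0.16) rose in 14 of 16 (15 adjusted over the list alone; adjusted p = 8.38e-06 and 0.259). PPAR targets and fatty acid oxidation genes rose in 12 of 28, with Acaa1a at 1.29 ± 0.082 (12 adjusted over the list alone; adjusted p = 0.00672 and 0.278).

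At 400 ppm of 1,4-DCB, 96 probes rose and 34 fell in liver, and 17.3% of the 704 probes called at 800 ppm were called from 400 ppm on. Cyp2b1 stood at 6.97 ± 0.54 (adjusted p = 2.57e-11), Cyp2b2 at 5.03 ± 0.48 (adjusted p = 3.71e-09), Cyp3a2 at 1.38 (adjusted p = 0.000181) and Aldh1a1 at 1.29 (adjusted p = 1.62e-07). The count of 130 was 61 without animal F502 and 75 with a filter at 20 CPM, which tests fewer probes.

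In kidney at 500 ppm of 1,2-DCB, Gstp1 and Pck1 were among the largest rises. Gstp1 rose from 163 ± 25 to 725 ± 240 CPM (SD, n = 9 and 5; 2.16 ± 0.14, adjusted p = 1.75e-14). Pck1, an enzyme of glucose synthesis, rose from 2440 ± 656 to 11700 ± 3830 CPM (2.27 ± 0.21, adjusted p = 3.41e-10). Slc51a, a bile acid and steroid transporter subunit, rose from 21.8 ± 5.56 to 136.9 ± 44 CPM (2.65 ± 0.24, adjusted p = 1.58e-10), whereas C3 fell from 108.2 ± 33.6 to 25.8 ± 14.4 CPM (-2.07 ± 0.29, adjusted p = 2.06e-06). For these 4 genes, 5 of 5 exposed animals lay beyond every control.

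By list, 1,2-DCB kidney showed rises in 18 and a fall in 1 of 29 NRF2 targets (the same adjusted over the list alone; adjusted p = 2.96e-11 and 0.000335). Probes of PPAR targets rose in 17 and fell in 2 of 31 (the same adjusted over the list alone; adjusted p = 4.63e-11 and 0.0138), with Acaa1a at 1.83 ± 0.15, Vnn1 at 1.76 ± 0.14 and Ehhadh at 1.24 ± 0.13. Conjugation enzymes rose in 9 of 15 (9 adjusted over the list alone; adjusted p = 3.55e-08 and 0.0062) and CAR and PXR targets in 6 of 18, with 1 fall (the same adjusted over the list alone; adjusted p = 0.000199 and 0.0182). Other lists fell and lost their call with an estimated correlation: 6 of 20 interferon probes, such as that of Isg15 (-1.88 ± 0.36), fell (12 adjusted over the list alone; adjusted p = 1.41e-05 and 0.15). So did 8 of 20 matrix genes, such as Col3a1 (-1.46 ± 0.22; 9 adjusted over the list alone; adjusted p = 0.000916 and 0.15). Cell cycle genes fell in 6 and rose in 1 of 41 (7 and 1 adjusted over the list alone; adjusted p = 0.00115 and 0.15). The unfolded protein list fell in 4 of 25 probes (7 adjusted over the list alone; adjusted p = 0.0355 and 0.293). Of 6 lymphocyte markers 1, Cd4, fell (-0.98; 3 adjusted over the list alone; adjusted p = 0.0291 and 0.0891).

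At 250 ppm of 1,2-DCB the kidney calls were Slc51a (1.33 ± 0.24, adjusted p = 0.00649) and Gstp1 (0.70 ± 0.14, adjusted p = 0.0141). The count of 2 was 0 without animal F501 and 1 without animal F502 or animal F504. At 10 ppm 8 probes rose and 1 fell, led by S100a4 (3.12 ± 0.48, adjusted p = 0.000501), S100a6 (2.15 ± 0.41, adjusted p = 0.00608) and the cyclooxygenase Ptgs1 (2.80 ± 0.47, adjusted p = 0.00131), all named after their values were seen. The count of 9 was 0 without animal F201, whose library stood apart from the other kidneys, 27 without animal F202, 21 without animal F204, 15 without animal F205 and 28 without control F8. It was also 0 with voom or in a fit of only that group and its controls.

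In kidney at 800 ppm of 1,4-DCB, the list of PPAR targets and fatty acid oxidation rose too. Cyp4a2, a fatty acid hydroxylase, rose from 2960 ± 645 to 7390 ± 2380 CPM (SD, n = 10 and 5; 1.32 ± 0.18, adjusted p = 3.49e-06) and Ehhadh from 52.9 ± 12.3 to 113.2 ± 8.36 CPM (1.10 ± 0.15, adjusted p = 4.13e-06). Ndrg1, a stress-induced gene, fell from 140000 ± 30800 to 51200 ± 7000 CPM (-1.45 ± 0.18, adjusted p = 3.07e-07). In these 3 genes, 5 of 5 exposed animals lay beyond every control. Probes of PPAR targets rose in 10 of 31 (16 rose and 1 fell adjusted over the list alone; adjusted p = 1.74e-13 and 0.00454). Cholesterol synthesis genes such as Insig1 (0.72 ± 0.11) rose in 5 and fell in 1 of 16 (10 and 1 adjusted over the list alone; adjusted p = 4.5e-07 and 0.00454). CAR and PXR targets rose in 5 of 18 (8 adjusted over the list alone; adjusted p = 0.000441 and 0.00454).

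Further lists in 1,4-DCB kidney passed only with the preset correlation. Fatty acid synthesis genes rose in 4 of 13, among them the regulator Srebf1 (1.08 ± 0.19; 4 rose and 1 fell adjusted over the list alone; adjusted p = 0.00503 and 0.167), although the list's median (-0.0074) and mean (-0.278) were below 0 while its test pointed up. Cell cycle genes fell in 5 of 42, with Kif22 at -1.74 ± 0.35 (11 adjusted over the list alone; adjusted p = 3.58e-05 and 0.0602). NRF2 targets rose in 5 of 29 (5 adjusted over the list alone; adjusted p = 0.0456 and 0.0592), conjugation enzymes in 1 of 15 (1 adjusted over the list alone; adjusted p = 0.0052 and 0.0633). Matrix genes fell in 1 of 20 (3 adjusted over the list alone; adjusted p = 0.00404 and 0.198). At 400 ppm the 5 calls were 3 probes of Cyp4a2 (0.96 ± 0.18 to 1.87, the smallest with adjusted p = 0.00563), Dbp (0.88 ± 0.14, adjusted p = 0.000577) and Nr1d2 (0.70 ± 0.16, adjusted p = 0.0416). That count was 2 without animal F504.

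Heart at 500 ppm of 1,2-DCB showed falls among matrix and cell cycle genes and rises among NRF2 targets. Col3a1, a fibrillar collagen, fell from 1760 ± 352 to 439 ± 99.2 CPM (SD, n = 10 and 5; -2.0 ± 0.21, adjusted p = 5.32e-09), and Col5a3 from 25.2 ± 3.56 to 3.87 ± 1.33 CPM (-2.70 ± 0.20, adjusted p = 2.53e-13). Bnip3, a mitophagy receptor, rose from 49.2 ± 9.07 to 160 ± 11.4 CPM (1.70 ± 0.12, adjusted p = 1.03e-13), and Myh7, the slow myosin heavy chain of the stressed rat heart, from 1380 ± 512 to 5470 ± 2220 CPM (1.98 ± 0.41, adjusted p = 0.000879). For these genes 5 of 5 exposed animals lay beyond every control. NRF2 targets rose in 13 of 25 (13 adjusted over the list alone; adjusted p = 8.37e-07 and 2.08e-05) and conjugation enzymes such as Gstz1 (1.00 ± 0.15) in 5 of 11 (5 adjusted over the list alone; adjusted p = 0.00123 and 0.00573). Cell cycle genes fell in 12 of 38, with Ccna2 at -2.93 ± 0.40 (16 fell and 1 rose adjusted over the list alone; adjusted p = 3.84e-06 and 0.00573), and matrix genes in 10 of 20 (12 adjusted over the list alone; adjusted p = 2.34e-08 and 0.0226). Interferon probes such as that of Oas1a (-1.69 ± 0.33, 4 of 5 animals below every control) fell in 8 of 20 (10 adjusted over the list alone; adjusted p = 1.11e-06 and 0.154).

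At 1 ppm of 1,2-DCB, 89 probes rose and 29 fell in heart, while 10 to 250 ppm gave 0. The largest rises at 1 ppm, named after their values were seen, were Car3 (6.30, adjusted p = 0.000433), the adipocyte hormone Adipoq (6.30), the smooth muscle gene Cnn1 (4.45) and Abcc3 (1.56, adjusted p = 0.000903). The libraries of animals F101 and F102 stood apart from the other hearts. Among controls and the 1 ppm group, F101 or F102 held the highest level of each of the 89 rises. Rises and falls together numbered 0 without the libraries standing apart, 3 without animal F101, 21 without animal F102, 213 without animal F103, 250 without animal F104 and 238 without animal F105. They numbered 64 without control F10, 58 without control F6, 77 without control F7 and 62 without control F8, and 0 in a fit of only that group and its controls.

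In heart at 800 ppm of 1,4-DCB, the cell cycle list fell on balance. Col5a3 fell from 25.5 ± 4.48 to 6.04 ± 1.56 CPM (SD, n = 10 and 5; -2.07 ± 0.16, adjusted p = 5.56e-13) and Ccna2 from 2.57 ± 0.778 to 0.579 ± 0.368 CPM (-2.13 ± 0.41, adjusted p = 0.000522). Tcap, a sarcomere protein, rose from 63.8 ± 16.5 to 135.5 ± 13.7 CPM (1.09 ± 0.17, adjusted p = 3.18e-05), and the monocyte attractant Ccl7 from 6.9 ± 2.61 to 15.9 ± 2.38 CPM (1.202 ± 0.25, adjusted p = 0.00143). Each lay beyond every control in 5 of 5 exposed animals. Cell cycle genes fell in 8 of 34 (11 adjusted over the list alone; adjusted p = 8.44e-08 and 0.0216) and NRF2 targets rose in 3 of 24 (3 adjusted over the list alone; adjusted p = 0.0252 and 0.0296). Matrix genes fell in 4 of 20 (5 adjusted over the list alone; adjusted p = 0.024 and 0.634) and of 7 glucocorticoid response genes Cdkn1a fell (1 adjusted over the list alone; adjusted p = 0.046 and 0.325). PPAR targets rose in 3 of 27 (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.0263 and 0.634). The PPAR list's median (0.13) and test pointed up and its mean (-0.39) down.

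Hepatocyte markers fell in 5 of 8 in 1,4-DCB heart (6 adjusted over the list alone; median -4.10, adjusted p = 0.0298 and 0.372). Alb (albumin) averaged 225 ± 334 CPM in controls and 7.01 ± 3.55 CPM at 800 ppm (-4.98 ± 1.43, adjusted p = 0.0274, 1 of 5 exposed animals below every control). Control F1, at 3.87 M counts the shallowest heart library, held the highest level of 27 of 30 abundant liver transcripts. Without controls F1 and F7, which stood apart, 0 of 8 hepatocyte markers were called by edgeR. Over all probes, 63 rose and 78 fell at 800 ppm, a count that was 83 without animal F603.

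Lung at 500 ppm of 1,2-DCB showed rises among NRF2 targets, while Isg15 and Col3a1 fell. Nqo1, a quinone reductase, rose from 10 ± 2.41 to 37 ± 2.26 CPM (SD, n = 10 and 4; 1.88 ± 0.15, adjusted p = 2.45e-12), Gstp1 from 117.2 ± 14.7 to 343 ± 92.1 CPM (1.55 ± 0.14, adjusted p = 6.75e-11) and Abcb1b from 13.6 ± 3.94 to 54.8 ± 26.1 CPM (2.01 ± 0.26, adjusted p = 4.96e-07). Isg15, an interferon-induced modifier, fell from 29.8 ± 13.4 to 5.55 ± 1.81 CPM (-2.41 ± 0.39, adjusted p = 4.41e-05) and Col3a1 from 1730 ± 383 to 642 ± 91.7 CPM (-1.43 ± 0.19, adjusted p = 9.86e-07). In these 5 genes, 4 of 4 exposed animals lay beyond every control. NRF2 targets rose in 19 and fell in 1 of 29 (21 and 1 adjusted over the list alone; adjusted p = 2e-19 and 2.26e-08). Conjugation enzymes rose in 5 and fell in 1 of 13 (8 and 1 adjusted over the list alone; adjusted p = 3.18e-05 and 0.00961). CAR and PXR targets rose in 7 of 15 (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.000142 and 0.0446). AhR targets rose in 3 of 5 (3 adjusted over the list alone, adjusted p = 0.00105 and 0.00961). These were Nqo1, which the NRF2 list also holds, Nfe2l2 (0.29, adjusted p = 0.0094) and Cyp1a2 (adjusted p = 0.0462), near 0 CPM in both groups. The AhR result is therefore not independent of the NRF2 result.

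Lists that fell in 1,2-DCB lung lost their call with an estimated correlation. Interferon probes fell in 11 of 20, with Oas1a at -1.65 ± 0.33 (12 adjusted over the list alone; adjusted p = 4.2e-11 and 0.109). Matrix genes fell in 6 of 20, with Sparc at -0.89 ± 0.14 (7 adjusted over the list alone; adjusted p = 3.06e-05 and 0.192), and fibroblast and smooth muscle markers in 2 of 8 (3 adjusted over the list alone; adjusted p = 0.0427 and 0.66). Cell cycle genes fell in 7 of 44, with Cdc20 at -0.84 ± 0.20 (7 adjusted over the list alone; adjusted p = 2.12e-06 and 0.131). Without animal F605, 61 probes rose and 58 fell, fewer than the 8.85% called with it. At 30 ppm the only call was the clock output gene Dbp (2.08 ± 0.37, adjusted p = 0.00736). This count was 0 without animal F304 or animal F305, with voom, or in a fit of only that group and its controls.

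In lung at 800 ppm of 1,4-DCB, changes beside the clock genes were smaller. Fcnb, a ficolin of neutrophils, stood at 8.11 ± 2.76 CPM in controls and rose to 20.2 ± 6.81 CPM (SD, n = 8 and 5; 1.32 ± 0.30, adjusted p = 0.00731, 4 of 5 animals above every control). The monocyte attractant Ccl7 rose from 7.08 ± 2.86 to 19 ± 3.69 CPM (1.42 ± 0.28, adjusted p = 0.00197, 5 of 5). Adm, a hypoxia-induced vasodilator, fell from 23.3 ± 6.69 to 11.5 ± 1.53 CPM (-1.02 ± 0.19, adjusted p = 0.00097, 5 of 5). Cholesterol synthesis genes such as Cyp51 (0.57 ± 0.11) rose in 3 of 16 (6 adjusted over the list alone; adjusted p = 3.15e-06 and 0.15). Cell cycle genes such as Ccnb2 (-0.90 ± 0.19, 2 of 5 animals below every control) fell in 8 of 45 (12 adjusted over the list alone; adjusted p = 3.15e-06 and 0.15). Of 7 glucocorticoid response genes Ddit4 and Mt2a fell (3 adjusted over the list alone; adjusted p = 0.0207 and 0.15). Of 2 red cell markers Alas2 rose (2 adjusted over the list alone; adjusted p = 0.0382 and 0.415). At 800 ppm 67 probes rose and 71 fell. That count was 83 without animal F605 and 32 with all libraries, which adds those the submitters marked as not used. With all libraries the 0 calls at 400 ppm became 367.

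Ovary at 500 ppm of 1,2-DCB showed the fewest changes among the tissues at that concentration. Ly86, a lymphocyte antigen, fell from 34.3 ± 7.84 to 17.3 ± 3.99 CPM (SD, n = 10 and 5; -0.99 ± 0.17, adjusted p = 0.000684), and the collagen chain Col6a3 from 390 ± 58.8 to 200.8 ± 25.9 CPM (-0.96 ± 0.16, adjusted p = 0.000684). The sialyltransferase St6galnac2 rose from 36 ± 6 to 68.1 ± 11 CPM (0.92 ± 0.15, adjusted p = 0.000684), with 5 of 5 exposed animals beyond every control for all 3. Cholesterol synthesis genes fell in 1 of 16, Hmgcs1 (-2.11 ± 0.51, 3 of 5 animals), but in 9 adjusted over the list alone (adjusted p = 4.85e-08 and 0.353). Interferon probes fell in 3 of 20 (7 adjusted over the list alone; adjusted p = 3.79e-05 and 0.353) and matrix genes in 3 of 20 (9 adjusted over the list alone; adjusted p = 7.42e-06 and 0.306). The count of 67 was 28 without animal F602, 33 without animal F603 and 25 without animal F604, and DESeq2 called 56 rises and 58 falls. Hmgcs1 itself was not called without F602, F603 or F604 or with voom. At 250 ppm the only call was the endothelial adhesion gene Sele (1.66 ± 0.31, adjusted p = 0.00953). That count was 3 without animal F503 and 0 without animal F504.

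In ovary at 800 ppm of 1,4-DCB, Hsd17b7 and A2m were among the largest rises. Hsd17b7, which acts in cholesterol and estradiol synthesis, rose from 221 ± 72.2 to 2160 ± 1360 CPM (SD, n = 10 and 5; 3.29 ± 0.35, adjusted p = 1.31e-07, 5 of 5 animals above every control). Lhcgr, the luteinizing hormone receptor, rose from 28.8 ± 8.45 to 102.4 ± 50.0 CPM (1.82 ± 0.30, adjusted p = 0.000168, 4 of 5) and A2m, a protease inhibitor, from 387 ± 228 to 1890 ± 905 CPM (2.29 ± 0.38, adjusted p = 0.00018, 4 of 5). Timp1, an inhibitor of matrix proteases, fell from 1740 ± 1060 to 486 ± 130 CPM (-1.84 ± 0.31, adjusted p = 0.00018, 5 of 5). Steroidogenesis and follicle genes rose in 3 of 17 (4 adjusted over the list alone; adjusted p = 0.00286 and 0.39) and granulosa and theca markers in 2 of 6 (4 adjusted over the list alone; adjusted p = 0.0166 and 0.231). Cholesterol synthesis genes such as Acat2 (1.26 ± 0.24, 4 of 5) rose in 4 of 16 (5 adjusted over the list alone; adjusted p = 0.000502 and 0.421). Fatty acid synthesis genes rose in 3 of 14 (4 adjusted over the list alone; adjusted p = 0.023 and 0.39) and interferon probes in 2 of 20 (3 adjusted over the list alone; adjusted p = 0.0203 and 0.435).

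The remaining lists that passed in 1,4-DCB ovary lost the call with an estimated correlation. Kidney injury genes, here Timp1, Tnfrsf12a, Cd44, Vim and Anxa2, fell in 5 of 13 (6 adjusted over the list alone; adjusted p = 0.0203 and 0.39), matrix genes such as Loxl2 (-1.17 ± 0.28) in 3 of 20 (3 adjusted over the list alone; adjusted p = 0.00582 and 0.39) and heat shock genes in 1 of 9, Hsp90aa1 (-0.81 ± 0.19; 4 adjusted over the list alone; adjusted p = 0.0203 and 0.39). The cell cycle list passed upward with 2 rises and 1 fall (Aurka) of 46 (the same adjusted over the list alone; adjusted p = 0.0282 and 0.912). The calls at 800 ppm, 8.47% of the probes, became 48 rises and 41 falls without animal F602, 63 and 38 without animal F603, and 78 and 49 without animal F604.

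**Figure D3:**
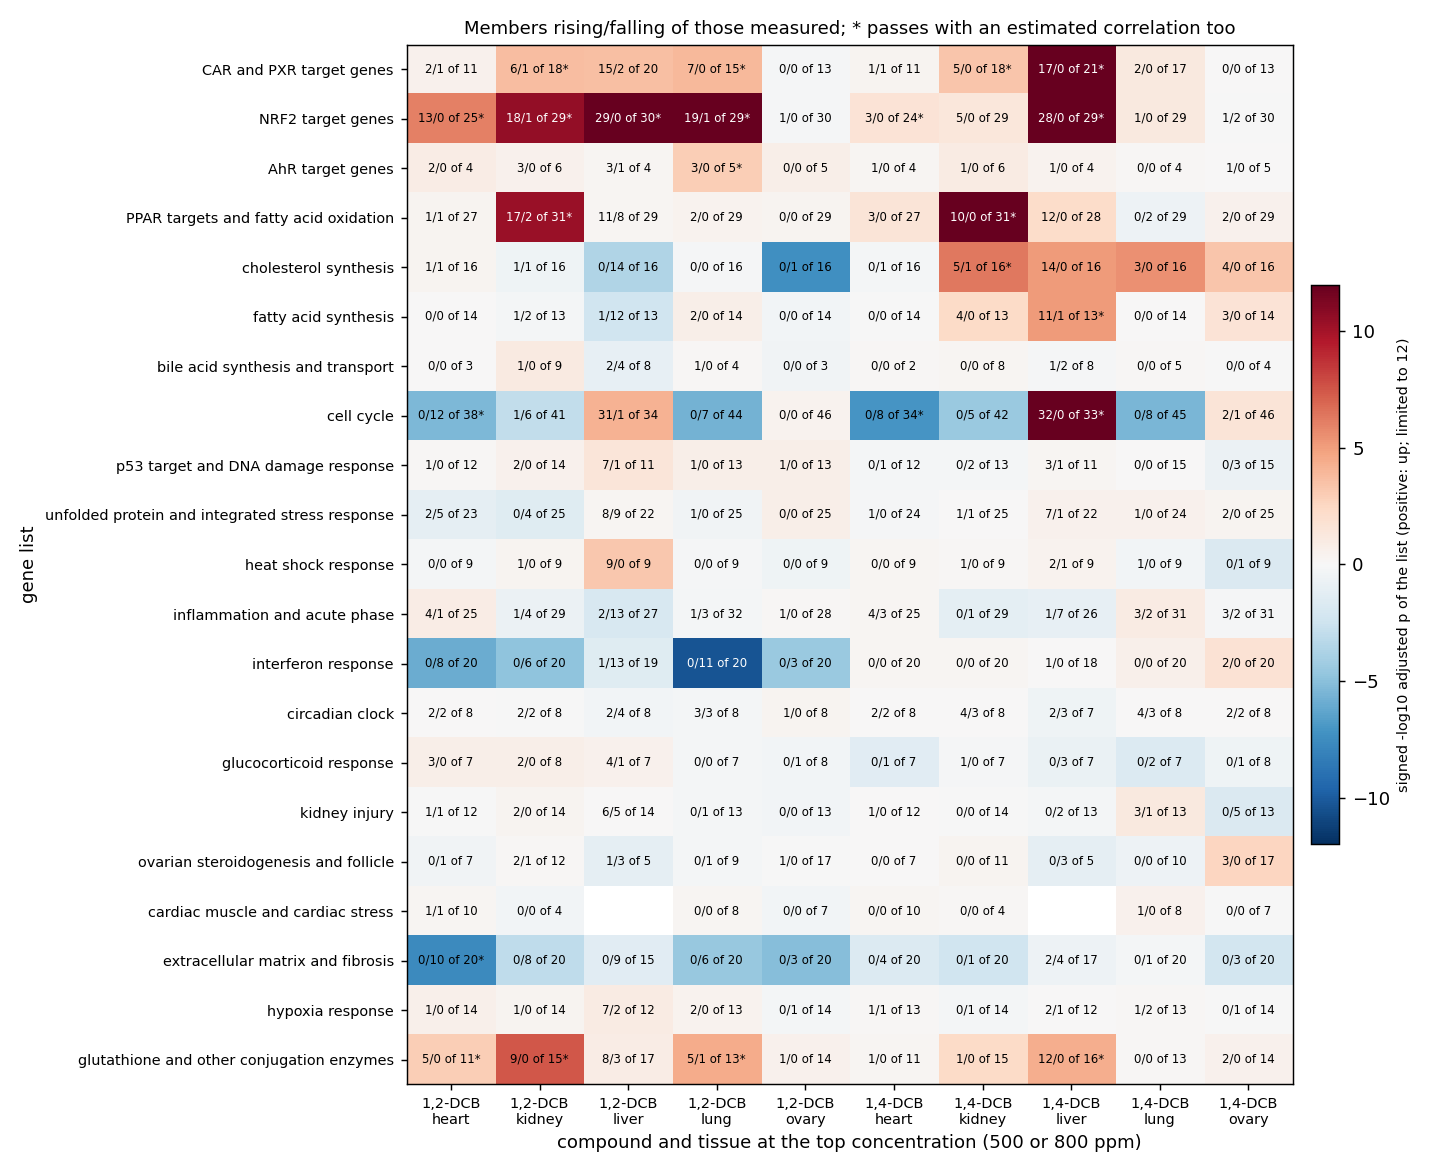
Gene lists (vertical axis) against tissue and compound at the top concentration (horizontal axis); the colour is the signed -log10 of the adjusted p of the camera test with the preset correlation, limited to 12. Each field gives the members called higher, those called lower and those measured, and a star marks lists that also pass with an estimated correlation. NRF2 targets reached 29 rises of 30 in 1,2-DCB liver and 28 of 29 in 1,4-DCB liver.

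Clock genes changed at the top concentration in nearly every tissue. Dbp, a clock output transcription factor, rose in all 10 pairs of tissue and compound, from 1.15 ± 0.29 in 1,2-DCB ovary (adjusted p = 0.0194, 3 of 5 animals above every control) to 4.06 ± 0.15 in 1,4-DCB lung (adjusted p = 5.7e-20, 5 of 5). In that lung group Dbp went from 39.6 ± 4.3 to 659.5 ± 113.9 CPM (SD, n = 8 and 5). Arntl (BMAL1) and Npas2, the activators of the clock loop, fell in all pairs except 1,2-DCB ovary. Arntl ranged from -0.65 ± 0.12 in 1,4-DCB liver to -3.47 ± 0.20 in 1,4-DCB kidney, and Npas2 from -0.55 ± 0.13 in 1,4-DCB ovary to -3.25 ± 0.30 in 1,2-DCB kidney. Nr1d2, a repressor of the loop, rose by 0.83 ± 0.16 in 1,2-DCB heart and by 2.14 ± 0.20 in 1,4-DCB lung. The 1,2-DCB ovary call of Dbp was lost without animal F603 or animal F604. The circadian clock list, whose members go both ways, passed its test in none of the 10 pairs.

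**Figure D4:**
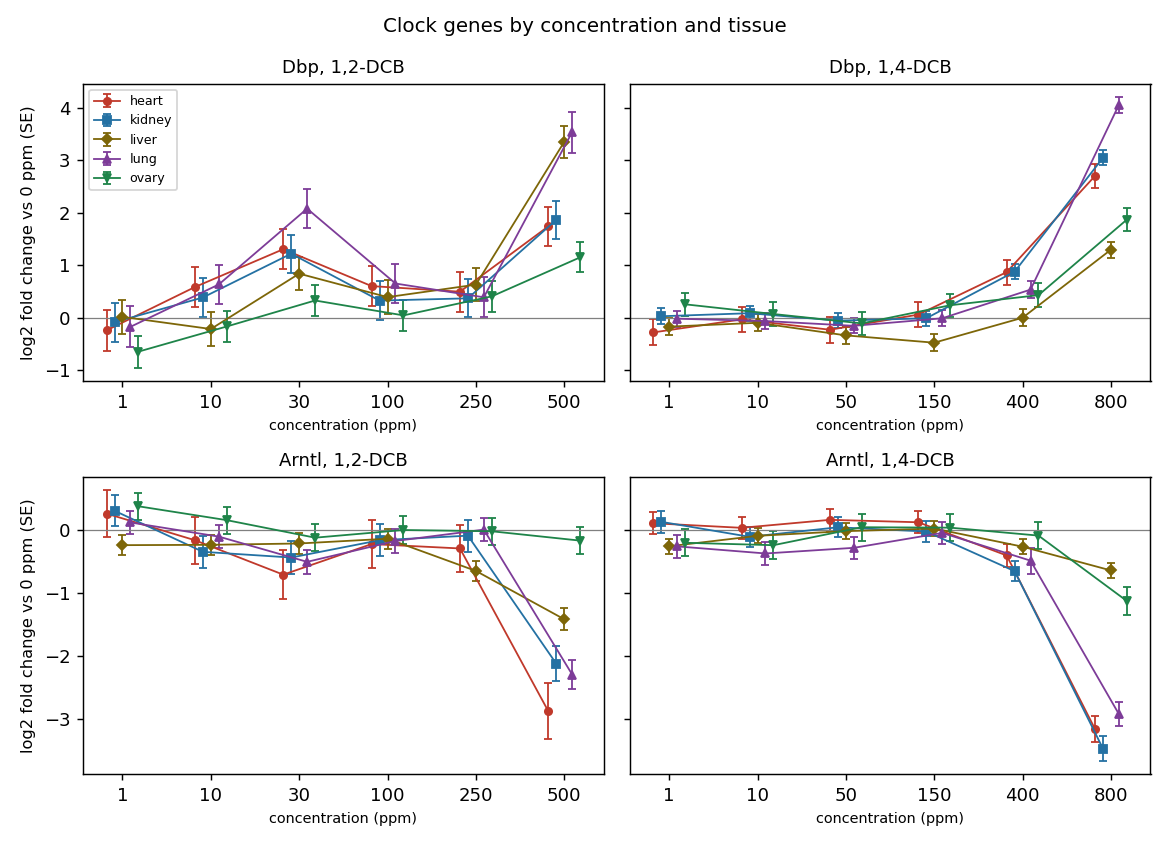
Log2 fold change against controls of Dbp and Arntl (vertical axis, bars are SE of the fit) against concentration in ppm (horizontal axis), a panel per gene and compound and a line per tissue, with 3 to 5 exposed and 8 to 10 control animals. Dbp in 1,4-DCB lung reached 4.06 at 800 ppm.

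Counts of 0 came from edgeR and do not exclude small changes. In heart, the 4 zero counts of 1,2-DCB had 3.49 to 6.26% of probes at an unadjusted p under 0.05, 0 to 3 calls by DESeq2 and 0 to 1 by voom. The 5 of 1,4-DCB had 4.33 to 9.74%, 0 to 9 and 0 to 5. In kidney, the 3 of 1,2-DCB had 4.27 to 9.9% unadjusted, 0 to 3 by DESeq2 and 0 by voom, and the 4 of 1,4-DCB 3.23 to 4.9%, 0 and 0. In liver, the 2 of 1,2-DCB had 4.31 to 8.17% and the 4 of 1,4-DCB 1.98 to 5.65% unadjusted, with 0 by DESeq2 and by voom. In lung, the 4 of 1,2-DCB had 1.69 to 4.68% unadjusted, 0 to 1 by DESeq2 and 0 to 1 by voom, and the 5 of 1,4-DCB 3.38 to 6.17%, 0, and 0 to 1. In ovary, the 4 of 1,2-DCB had 1.96 to 11% unadjusted, 0 to 10 by DESeq2 and 0 by voom, and the 5 of 1,4-DCB 2.05 to 7.42%, 1 to 2, and 0.

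The compounds, which differ in the position of their chlorine atoms, were compared by the difference of their changes. At 500 ppm of 1,2-DCB against 400 ppm of 1,4-DCB, which are different concentrations, the change was higher with 1,2-DCB in 561 probes and lower in 541 in liver, in 69 and 83 in kidney, in 65 and 54 in heart, in 34 and 39 in lung, and in 19 and 17 in ovary. In liver the change was larger with 1,2-DCB for Cbr1 (difference 2.95, 95% interval 2.68 to 3.21, adjusted p = 3.36e-31), Hspb1 (4.79, 4.18 to 5.40, adjusted p = 7.14e-22), Gstp1 (4.36, adjusted p = 9.08e-12) and Gsta2 (1.28, 0.818 to 1.74, adjusted p = 2.93e-06). It was lower with 1,2-DCB for Cyp51 (-2.29, -2.72 to -1.86, adjusted p = 1.15e-14), Fasn (-2.16, adjusted p = 6.85e-09) and Cyp2b1 (-2.59, -4.21 to -0.981, adjusted p = 0.00536), while Cyp3a2 did not pass (-0.58, -1.34 to 0.173, adjusted p = 0.196). Elsewhere the leading differences were Gstp1 (2.47, 2.09 to 2.84, adjusted p = 3.54e-17) and Slc51a (2.77, adjusted p = 1.99e-09) in kidney, Bnip3 (1.62, 1.3 to 1.94, adjusted p = 4.3e-12) and Col3a1 (-1.90, adjusted p = 5.11e-08) in heart, Npas2 (-2.26, adjusted p = 9.7e-13) and Nqo1 (1.77, adjusted p = 3.39e-06) in lung, and Col6a3 (-1.19, -1.62 to -0.765, adjusted p = 0.00106) in ovary. Cyp4a2 in kidney (-0.28, -0.864 to 0.298, adjusted p = 0.677) and Hsd17b7 in ovary (1.71, 0.206 to 3.22, adjusted p = 0.233) did not pass. The heart count was 79 without 1,2-DCB animal F602 and the lung count 43 without 1,4-DCB animal F501. With all libraries the lung count was several times larger, with more probes lower than higher. The ovary count was 21, 7 and 16 without 1,2-DCB animals F602, F604 and F605. It was 22 and 12 without 1,4-DCB animals F501 and F502.

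At the matched 1 and 10 ppm, edgeR called 0 differences between the compounds in kidney, liver, lung and ovary, with 1.68 to 8.27% of probes at an unadjusted p under 0.05 and 0 calls by voom. Intervals bounded some of the differences: in liver Cyp51 differed by 0.12 (-0.299 to 0.548) at 1 ppm and 0.24 (-0.183 to 0.664) at 10 ppm, and Cyp2b1 by 0.15 (-1.72 to 2.01) and 1.49 (-0.25 to 3.24). Kidney Gstp1 differed by 0.16 (-0.227 to 0.538) at 1 ppm and -0.08 (-0.443 to 0.292) at 10 ppm, and lung Nqo1 by 0.11 (-0.357 to 0.58) at 1 ppm. An interval within 1 log2 unit of 0 was found at 1 and 10 ppm for 76.8 and 65.6% of the genes named in liver, 71.6 and 70.4% in kidney, 68.8 and 62.5% in lung, and only 44.3 and 54.3% in ovary. In heart 22 probes differed at 1 ppm, led by Abcc3, and 25 at 10 ppm, led by liver transcripts such as Cyp1a2 and Mug1. Both heart counts were 0 without the libraries standing apart. Leaving out 1,2-DCB animals F101, F102, F103, F104 and F105 in turn gave 1, 12, 84, 97 and 82 at 1 ppm, and 13 came without 1,4-DCB animal F104. At 10 ppm the count was 0 without 1,2-DCB animal F201, and 13, 8, 9 and 11 without 1,4-DCB animals F202, F203, F204 and F205. For kidney at 10 ppm it was 4 without 1,2-DCB animal F202, F204 or F205. Controls of the compounds differed in 63 probes in heart, 31 in lung, 15 in ovary and 14 in liver. With voom each of these counts moved by over 1.5 times, in ovary to 0. In kidney 0 probes differed (140 at an unadjusted p under 0.05, 0 by voom).

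Called probes overlapped between the compounds at their top concentrations. In liver 260 probes rose with both compounds against 134.1 expected (one-sided Fisher exact p = 1.78e-48), among them Cbr1, Akr7a3 and Abcb1b, and 212 fell with both against 102.6 expected (p = 3.1e-44). Opposite moves in liver were fewer than expected: 25 rose with 1,2-DCB and fell with 1,4-DCB against 105.9 expected, and 62 fell with 1,2-DCB and rose with 1,4-DCB against 129.9, including the cholesterol and fatty acid synthesis genes Cyp51, Lss, Fdps, Fasn and Acly. In kidney 30 rose with both against 4.89 expected (p = 1.72e-18), such as Vnn1 and Ehhadh, and 25 fell against 4.87 (p = 5.71e-13), such as C3 and C4a. In heart 23 rose against 3.33 (p = 7.03e-15) and 35 fell against 5.04 (p = 3.42e-23), such as Col5a3, Loxl1 and Ccna2. In lung 14 rose against 2.78 (p = 2.7e-07) and 19 fell against 3.34 (p = 1.46e-10). In ovary 12 rose against 1.54 (p = 9.63e-09) and 5 fell against 1.34 (p = 0.00938). At the stricter threshold of 0.01, 0 falls were shared in ovary, where 0.073 were expected. Outside liver, opposite moves numbered 1 in heart, 0 in kidney, 1 in lung and 1 in ovary. The shared probes include clock genes: Dbp and Nr1d2 rose and Npas2 and Arntl fell with both compounds in heart, kidney and lung. Dbp also rose with both in ovary. Their shift cannot be told apart from a difference in the hour of collection. The Fisher test also treats probes as independent, which genes that move together are not.

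Tissues were compared for genes named in liver and in the other tissue. With 1,2-DCB, the change differed from liver in 9 of 15 genes for heart, 7 of 21 for kidney, 10 of 18 for lung and 2 of 2 for ovary. With 1,4-DCB, it differed in 6 of 9 for heart, 9 of 13 for kidney, 5 of 10 for lung and 5 of 8 for ovary. The joint fit has its own normalization, so tested differences are not plain subtractions of the changes above and mostly lay lower. Mdm2 changed by 1.93 in 1,2-DCB liver and 0.26 in heart, with a tested difference of 1.47. Calls of small differences, such as Psmb9 in 1,2-DCB kidney (-0.49, adjusted p = 0.0352, with changes of -1.045 in liver and -0.70 in kidney), may depend on this. Opposite directions were found for Gstz1, which fell in 1,2-DCB liver and rose in heart (difference -2.03, adjusted p = 1.43e-24) and lung (-1.68, adjusted p = 1.29e-17), and for Racgap1, a division gene, which rose in 1,4-DCB liver and fell in heart (4.00, adjusted p = 1.09e-13). Pck1 fell in 1,4-DCB liver and rose in kidney (-3.0, adjusted p = 0.0131). With the animal as a replicate block, the difference passed for Nqo1 in 1,2-DCB kidney (adjusted p = 0.0389, against 0.104 without the block), Arntl in 1,2-DCB lung (0.0441 against 0.152) and Vnn1 in 1,4-DCB ovary (0.0175 against 0.0573), and no longer passed for Fga in 1,4-DCB heart (0.0646 against 0.00743).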

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

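The tests of fat, connective tissue, liver RNA, collection hour and exposure along the concentrations, and the splits of 1,2-DCB heart at 1 and 500 ppm, 1,2-DCB kidney at 10 ppm and the control livers, were chosen only after the results were seen. The clock genes drew attention because Dbp and Arntl shifted at the top concentration in nearly all tissues at once. Of the 100 probes nearest in control level, a median of 2% moved as far as a clock gene. The clock genes were picked because they had moved, so a small share was likely from the start. It therefore does not decide on a difference in depth, which stays open. The hour of collection and exposure acting with concentration also stay open and cannot be told apart. By the hour, 1 of 35 animals at lower 1,2-DCB concentrations, at 30 ppm with a mean Dbp minus Arntl score of 3.16, reached the lowest animal at 500 ppm (3.10), and 0 of 35 reached the lowest at 800 ppm of 1,4-DCB (4.53). By concentration, the score moved the same way at the next lower concentration in 10 of 10 pairs, but the median ratio to the top was 0.172 (0.0652 to 0.329), and with 1,2-DCB Dbp stood higher at 30 ppm (2.08 in lung, 1.31 in heart) than at 100 ppm (0.65 and 0.61) or 250 ppm (0.39 and 0.50), though in ovary it was lower at 30 than at 250 ppm (0.33 and 0.41).

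The 89 rises and 29 falls called in heart at 1 ppm of 1,2-DCB stood out because no probe was called from 10 to 250 ppm. Without animals F101 and F102, 21.7% of the median change (0.614) was kept (0.133). The probes had been called with these animals in the group, so a drop was built in. This share therefore does not decide on an effect of 1 ppm on every animal. Fat stays open, since adipocyte markers went both ways (median -0.409 against other hearts in F102, with Adipoq among the largest rises). Connective tissue or vessel wall in these pieces of heart also remains a candidate explanation, with a median marker at 2.03 in F101 and 0.461 in F102, while hepatocyte markers (1.95 and 1.27) and striated muscle markers (-0.652 and -1.26) moved too and were not tested as explanations. Depth stays open, since 1 of the 2 totals, 12.6 M in F102, lies within the controls (8.55 to 16.5 M) and 20.7 M in F101 does not.

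Liver transcripts in 1,4-DCB control hearts may come from liver RNA that entered control F1: 27 of 30 abundant liver transcripts were highest there, at a median of 0.788% of their liver level (0.396 to 2.42%). Alb, Fga and Mug1 were among the most abundant. Loss of hepatocyte transcripts on exposure to 1,4-DCB stays open: 0 of 8 hepatocyte markers were called without controls F1 and F7, but with fewer controls a lost call excludes nothing while the median change stays large (-4.10 before and -2.75 after). In the sum of these transcripts, 6 of 10 controls lay at or below the highest 800 ppm library. That sum mostly follows Tf, at a median of 1070 CPM in these hearts against 38.9 CPM for Fgg, the next highest. It therefore says little on the other transcripts. No biological explanation beyond exposure was tested.

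For each count above 0, 100 splits of the same libraries into groups of the same sizes were drawn, the real one included. Chance can be excluded at the top concentration of both compounds, where the real count stands before the highest of the other splits. For 1,2-DCB these are 250 and 1.1e+02 in heart, 388 and 1.4e+02 in kidney, 1368 and 951 in liver, 2.0e+02 and 49 in lung, and 67 and 1 in ovary. For 1,4-DCB they are 1.4e+02 and 25 in heart, 1.2e+02 and 18 in kidney, 704 and 314 in liver, 1.4e+02 and 36 in lung, and 2.0e+02 and 23 in ovary. It can also be excluded in liver at 250 ppm of 1,2-DCB (500 and 174) and at 400 ppm of 1,4-DCB (130 and 11). In liver at 100 ppm of 1,2-DCB (43 and 13) the count was 12 without animal F403, so that chance is not safely excluded there. The real count was also the highest for the controls of both compounds in heart (63 and 37), liver (14 and 2) and lung (31 and 2). But with voom the heart count fell below the highest other split and the liver count fell too. With all libraries the lung count fell as well. Chance is therefore not safely excluded among these controls. In each of these cases 1 split of 100, the real one, gave the count. That was also so for the compound difference in heart at 10 ppm (25 and 8), but this count is 0 without 1,2-DCB animal F201 and with voom, so that chance is not safely excluded there.

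Other splits sometimes reached or passed the real count. The compound difference at 500 against 400 ppm stayed under 5 splits in heart (2 splits of 100 as large, 1.2e+02 and 1.4e+02), kidney (3, 1.5e+02 and 177) and liver (2, 1102 and 1116). The median of the other splits was 0, 0 and 2 there, but the highest passed the real count. The splits alone do not safely exclude chance for these differences. Heart at 1 ppm (3; 1.2e+02 and 1.5e+02), kidney at 250 ppm (4; 2 and 3) and ovary at 250 ppm (4; 1 and 29) of 1,2-DCB and the compound difference among control ovaries (2; 15 and 24) also stayed under 5 splits. But the heart count at 1 ppm is 3 without animal F101, those of kidney and ovary at 250 ppm are 0 without 1 animal, and voom gives 0 among control ovaries. Some of 31 counts would also stay under 5 splits by chance, so that chance is not safely excluded in these cases. Chance cannot be excluded for 1,2-DCB kidney at 10 ppm (10; 9 and 43), liver at 10 ppm (14; 1 and 36) and lung at 30 ppm (9; 1 and 5), for 1,4-DCB kidney at 400 ppm (15; 5 and 58), or for the compound difference in heart at 1 ppm (21; 22 and 1.2e+02) and in lung at 500 against 400 ppm (7; 73 and 206). Splits that call several times the real count, as in these 6 and in ovary at 250 ppm, point to a structure of the samples, but which libraries drive them was not tested. For the 49 counts of 0 the splits decide nothing, since 100 of 100 give at least 0.

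In groups of 4 to 10 libraries, chance alone marks about 1 in 20 for a value far from the others. Of 69 groups of totals, 4 held such a library: animal F301 in 1,2-DCB lung at 30 ppm with 22.6 M counts, F403 in 1,2-DCB ovary at 100 ppm with 23.1 M, F503 in 1,2-DCB kidney at 250 ppm with 47.1 M, and control F9 in 1,4-DCB lung with 18.6 M. Of 1.2e+02 groups of gene levels, 23 held one. Among 1,2-DCB hearts these were Dbp in control F8 (405.2 CPM), Arntl in control F2 (129.7 CPM), and Npas2 in control F1 (31.1 CPM) and in animal F603 (5.92 CPM). In 1,2-DCB kidney they were Hmox1 in F604 (1156 CPM), Rup2 in control F9 (261 CPM) and Npas2 in control F3 (33.3 CPM), in 1,2-DCB liver Rup2 in control F8 (11840 CPM) and in F605 (3263 CPM), in 1,2-DCB lung Npas2 in control F7 (62.7 CPM) and Arntl in F603 (8.34 CPM), and in 1,2-DCB ovary F3 and Mx1 in control F8 (18.8 and 102.8 CPM). Among 1,4-DCB hearts they were Dbp in F601 (876 CPM), Serpina1 in control F1 (193 CPM) and in F604 (2.3 CPM), and Mug1 in control F1 (570 CPM). In 1,4-DCB kidney it was Hmox1 in F602 (742 CPM), in 1,4-DCB liver Igfbp1 in control F1 (98.7 CPM), in 1,4-DCB lung Dbp in control F4 (29.9 CPM) and Arntl in control F7 (173 CPM), and in 1,4-DCB ovary Fosl1 and Plaur in control F5 (1320 and 1166 CPM).

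In some libraries that the submitters marked as not used, and that are not used here either, changes named at the top concentration lay beyond all controls. Of the 8 largest rises in the tissue these were 3 in animal F601 of 1,2-DCB lung at 500 ppm (Dbp, Abcb1b and Gstp1), 4 in F204 of 1,4-DCB lung at 10 ppm (Dbp, Nr1d2, Fcnb and S100a4) and 3 in F504 of 1,4-DCB lung at 400 ppm (Dbp, Ier3 and Bhlhe40), where chance gives 0.727, 0.889 and 0.889. Of the 8 largest falls they were 0, 5 and 3. Unused libraries without exposure, or with hardly any counts, did so as well: a control kidney of 1,2-DCB had 3 rises and 2 falls, control lungs F2 and F8 of 1,4-DCB 2 rises each with 3 and 2 falls, and F102 of 1,4-DCB lung at 1 ppm, with 0.00768 M counts, 0 rises and 7 falls. These values therefore do not separate exposure from the quality of the libraries.

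Differences between the compounds passed in heart at 1 ppm (18 probes higher and 4 lower with 1,2-DCB) and at 10 ppm (25 higher), and at 500 against 400 ppm in heart (65 and 54), kidney (69 and 83), liver (561 and 541), lung (34 and 39) and ovary (19 and 17). Genes whose change differed between liver and heart, kidney, lung and ovary numbered 9, 7, 10 and 2 with 1,2-DCB and 6, 9, 5 and 5 with 1,4-DCB. Opposite directions in liver and another tissue were found with 1,2-DCB for Gstz1 against heart (-2.03) and lung (-1.68) and for Cyp1a2 against lung (-5.70, near 0 CPM in lung, where its call was lost under 12 alternatives), and with 1,4-DCB for Racgap1 against heart (4.00), Pck1 against kidney (-3.0), C3 against lung (-1.42), and Aurka (2.77) and Hp (-2.44) against ovary.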

How the results depend on the processing

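Dividing by the probe step, leaving out libraries standing apart and leaving out single controls were chosen only after the data were seen. Of 1577 recomputed counts 1421 stayed within 1.5 times the reported count and the others moved. Of the 80 reported counts 49 were 0, and a 0 that stayed 0 is among those that stayed. The share therefore says little on counts above 0, some of which moved widely without 1 library, as given below. Of 11256 recomputed gene tests 10561 kept their side of the threshold, 695 lost it and 0 reversed. Under every alternative, 351 of 512 named genes passed. DESeq2's size factors in edgeR moved 0 of 80 counts. Both normalizations assume that most probes are unchanged. In liver at 500 ppm of 1,2-DCB, where 67.8% were called, their comparison therefore cannot test the normalization. Of 96 tissue differences refitted with the replicate block 92 kept their call, and apart from the 4 given with their values above no call changed. Small changes are often missed: in simulation 38.8 to 67.2% of 1.5-fold changes against controls, 22.4 to 42.9% of such differences between the compounds, and 0% (20.9% with the replicate block) between liver and kidney were recovered. Where a count moved, the cause was not tested, except that a filter at 20 CPM tests fewer probes and a stricter threshold calls fewer.

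DESeq2 gave, for 1,2-DCB, 1, 1 and 3 in heart at 10, 30 and 100 ppm, 22, 3 and 4 in kidney at 10, 30 and 250 ppm, 2 in liver at 10 ppm, 1 in lung at 100 ppm, and 10, 1, 2 and 1.1e+02 (56 rises and 58 falls) in ovary at 1, 30, 100 and 500 ppm; for 1,4-DCB, 3, 3 and 9 in heart at 10, 50 and 400 ppm and 2, 1, 1, 1 and 2 in ovary at 1, 10, 50, 150 and 400 ppm. Voom gave 1, 0, 27, 0 and 1 in 1,2-DCB heart at 100, kidney at 10, liver at 100, lung at 30 and lung at 100 ppm, 5 and 1 in 1,4-DCB heart and lung at 400 ppm, 9, 0 and 25 for the compound difference in heart at 1 ppm, 10 ppm and among controls, and 5, 52 and 0 among control livers, lungs and ovaries. A filter at 20 CPM gave 1, 2, 0 and 0 in 1,2-DCB heart at 100, kidney at 10, liver at 10 and ovary at 250 ppm, 25, 210 and 4.0e+02 (207 rises and 195 falls) in liver at 100, 250 and 500 ppm, and for 1,4-DCB 2 in heart and 3 in kidney at 400 ppm, 77 in kidney at 800 ppm, and 75 and 257 in liver at 400 and 800 ppm. No filter gave 39 for the heart difference at 10 ppm. Fits of only the exposed group and its controls gave 0 in 1,2-DCB heart at 1, kidney at 10, lung at 30 and ovary at 250 ppm, 23 in liver at 100 ppm, 1.2e+02 (62 rises and 63 falls) in ovary at 500 ppm, and 2 and 3 in 1,4-DCB heart and kidney at 400 ppm. All libraries gave 1 in 1,2-DCB kidney at 250 ppm, 367 and 32 in 1,4-DCB lung at 400 and 800 ppm, and 3.0e+02 (88 higher and 216 lower with 1,2-DCB) and 4 for the lung difference at 500 against 400 ppm and among controls. Dividing by the step gave 1 in 1,2-DCB heart at 100 ppm. Without libraries standing apart there were 0 in 1,2-DCB heart at 1 ppm and kidney at 10 ppm, 0, 0 and 41 for the heart difference at 1 ppm, 10 ppm and among controls, and 1 for the kidney difference at 1 ppm and among controls. A threshold of 0.01 left 12 shared rises and 14 shared falls in heart, 17 and 12 in kidney, 4 and 6 in lung, and 5 and 0 in ovary.

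Leaving out 1 library at a time gave, for 1,2-DCB, 3 to 250 in heart at 1 ppm, 0 to 28 in kidney at 10 ppm, 0 to 2 in kidney at 250 ppm, 1 to 4 and 12 to 52 in liver at 10 and 100 ppm, 0 to 1 and 1.2e+02 (61 rises and 58 falls) to 212 in lung at 30 and 500 ppm, and 0 to 3 and 25 to 81 in ovary at 250 and 500 ppm. For 1,4-DCB it gave 83 to 162 in heart, 83 to 163 in lung and 89 to 267 in ovary at 800 ppm, and 2 to 6 in kidney and 61 to 1.4e+02 in liver at 400 ppm. The compound difference ran from 1 to 97, 0 to 29 and 79 to 130 in heart at 1 ppm, 10 ppm and 500 against 400 ppm, from 43 to 74 in lung and 7 to 46 in ovary at 500 against 400 ppm, and from 0 to 4 in kidney at 10 ppm. Counts of 0 became 1 in 1,2-DCB heart at 10 ppm without control F7 or animal F204 or F205, 3 and 1 at 30 ppm without F301 and F302, 1, 1 and 3 at 100 ppm without controls F10, F2 and F9, and 1 at 250 ppm without F503; 1 in kidney at 30 ppm without F304; 1 in lung at 100 ppm without control F1, control F8 or F401; and 4 and 14 in ovary at 1 ppm without control F2 and F104 and 1 at 30 ppm without F304. In 1,4-DCB at 400 ppm they became 1, 1, 5 and 4 in heart without controls F10, F3 and F8 and animal F501, 1 in lung without F503, and 1 and 2 in ovary without controls F10 and F9.

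With an estimated correlation, 23 of 70 list calls stayed past the threshold and 47 did not, with these adjusted p. For 1,2-DCB they were 0.154 (interferon) in heart; 0.15 (cell cycle, interferon, matrix), 0.293 (unfolded protein) and 0.0891 (lymphocytes) in kidney; 0.108 (CAR and PXR), 0.265 (cholesterol, cell cycle), 0.242 (fatty acid synthesis), 0.172 (p53, heat shock), 0.174 (inflammation), 0.414 (interferon), 0.319 (matrix) and 0.197 (hepatocytes) in liver; 0.131 (cell cycle), 0.109 (interferon), 0.192 (matrix) and 0.66 (fibroblasts) in lung; and 0.353 (cholesterol, interferon) and 0.306 (matrix) in ovary. For 1,4-DCB they were 0.634 (PPAR, matrix), 0.325 (glucocorticoid) and 0.372 (hepatocytes) in heart; 0.0592 (NRF2), 0.167 (fatty acid synthesis), 0.0602 (cell cycle), 0.198 (matrix) and 0.0633 (conjugation) in kidney; 0.278 (PPAR) and 0.259 (cholesterol) in liver; 0.15 (cholesterol, cell cycle, glucocorticoid) and 0.415 (red cells) in lung; and 0.421 (cholesterol), 0.39 (fatty acid synthesis, heat shock, kidney injury, steroidogenesis, matrix), 0.912 (cell cycle), 0.435 (interferon) and 0.231 (granulosa) in ovary. Without the exposed libraries of highest and lowest total, 60 of 70 calls held, and the others had 0.0825 (interferon) and 0.0906 (matrix) in 1,2-DCB liver, and in 1,4-DCB 0.317 (PPAR), 0.0744 (glucocorticoid) and 0.104 (hepatocytes) in heart, 0.121 (NRF2) in kidney, and 0.0927 (fatty acid synthesis), 0.952 (cell cycle), 0.0839 (heat shock) and 0.0596 (kidney injury) in ovary.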

Other observations

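Of the tests given here, both on food intake were chosen only after the results were seen; the gene lists and comparisons had been planned. In liver at 500 ppm of 1,2-DCB, some lists moved both ways. Of 22 probes of the unfolded protein and integrated stress response list, 8 rose and 9 fell (8 and 9 adjusted over the list alone). Among the rises, asparagine synthetase Asns went from 0.71 ± 0.156 to 9.12 ± 3.42 CPM (SD, n = 10 and 5; 3.67 ± 0.21, adjusted p = 4.65e-18) and the kinase-like regulator Trib3 from 0.522 ± 0.148 to 6.85 ± 3.49 CPM (3.69 ± 0.25, adjusted p = 5.48e-16), each in 5 of 5 exposed animals above every control. Pdia6 and Calr, folding helpers of the endoplasmic reticulum, were among the 9 that fell. The list itself did not pass (adjusted p = 0.553), its median was -0.05 and its mean 0.70, and its test pointed up. Bile acid genes also moved both ways: of 8 measured members 4 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.11), with the bile salt export pump Abcb11 falling from 61.4 ± 4.98 to 24.5 ± 2.61 CPM (-1.32 ± 0.077, adjusted p = 7.75e-18) and the uptake carrier Slco1b2 from 138.6 ± 14.3 to 47.4 ± 14.5 CPM (-1.55 ± 0.13, adjusted p = 4.12e-13), each in 5 of 5 animals.

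Markers of resident immune cells moved in liver as well. Macrophage and monocyte markers fell in 5 of 5 at 500 ppm of 1,2-DCB (5 adjusted over the list alone; median -1.02, adjusted p = 0.0566) and in 3 of 5 at 800 ppm of 1,4-DCB (3 adjusted over the list alone; median -0.36, adjusted p = 0.244), so that neither list passed. In 1,4-DCB liver, Abcg5, a sterol exporter, fell from 3.43 ± 0.964 to 0.736 ± 0.3 CPM (-2.25 ± 0.30, adjusted p = 1.45e-07, 5 of 5 animals below every control), while cholesterol synthesis genes rose.

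A hypothesis was tested for the fatty acid oxidation genes that rose in kidney with both compounds: animals at the top concentration may have eaten less, in which case fatty acid synthesis genes would fall in liver and Pck1 would rise there. For 1,4-DCB the liver moved against this prediction: 11 of 13 fatty acid synthesis genes rose, and Pck1 (-1.81) and Igfbp1 (-2.15) fell. Fgf21, a fasting-induced hormone near 0 CPM in controls, rose however (1.70, adjusted p = 0.00415). Exposure changed many other transcripts of the same livers, so these genes may not report feeding, and lower food intake stays open. For 1,2-DCB lower food intake stayed open, because 12 of the 13 fell and Fgf21 rose by 3.18, but Pck1 did not pass (-0.89, adjusted p = 0.313) and hepatocyte markers fell too. Food intake and body weight were not analysed here.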
